A study of Mus musculus with 6 samples.

How the data were processed

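Droplet single-cell RNA libraries of mouse colon cells were made with 10x chemistry from live sorted cells, per the labels' protocols, which name both 5′ and 3′ kits and a G4 sequencer. The authors deposited, for each of the 6 libraries, a matrix of counts of unique molecular identifiers (UMIs) per gene and barcode. Per the submitters' processing notes these counts came from Cell Ranger 7.0.1 with the mm10 mouse genome. Which kit was used for which library is not given in the sources used here. The matrices held whole numbers only, 32285 genes each, and no barcode with fewer than 500 UMIs. Gene symbols were those in the files; 32158 gene identifiers were found in the GENCODE M21 annotation of the same genome build, which gave the coordinates. Symbols shared by more than 1 identifier (40) were kept apart by identifier.

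Each library was 1 group: macrophages of BM mice, macrophages of GVHD mice, macrophages of WT recipients, macrophages of IL34KO recipients, T cells of WT recipients and T cells of IL34KO recipients. The labels gave the groups, and no animal, batch or replicate was named. With 1 library per group no test was made, and no p-value, standard error or count of changed genes was computed. Macrophage and T-cell libraries of a recipient type were sorted for different cells, and whether they come from the same mice is not given in the sources used here, so they were not taken as replicates. The 3 comparisons were GVHD against BM macrophages, IL34KO against WT macrophages and IL34KO against WT T cells.

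Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. Doublets were scored with Scrublet at an expected rate of 0.8% per 1000 barcodes. Its automatic threshold marked 0, 0, 0 and 3 barcodes in the 4 macrophage libraries, which is too few to have worked, so the 216, 90, 339 and 463 barcodes with the highest scores, the expected number, were removed there. In the T-cell libraries the automatic calls (1075 and 687 barcodes) were used. Counts were scaled to 10000 per cell and logged, 2000 variable genes were chosen without immunoglobulin, T-cell receptor, mitochondrial, ribosomal, Xist and Y-linked genes, and 30 principal components and 15 neighbours went into Leiden clustering at resolution 1. The macrophage libraries were clustered together and the T-cell libraries together, without batch integration. A cluster was called X-like from 18 marker sets, requiring at least 3 markers detected in at least 25% of its cells. It stayed unnamed where its top 10 genes went against the name or its depth was low with no such marker among them. The macrophage comparisons used the monocyte/macrophage-like cells and the T-cell comparison the T cell-like cells.

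UMIs were summed over the cells of a class and library and divided by the class total, as counts-per-million (CPM). Ratios carry exact 95% conditional binomial intervals, levels exact Poisson intervals and shares exact Clopper-Pearson intervals. All of these cover counting error only, not differences between animals or preparations. The floor for a count of 0 was 3 counts. For 28 gene lists (10 for macrophages, 10 for T cells and 8 for both), members with at least 5 CPM in 1 of the 2 libraries counted as measured. The median log2 ratio of the measured members was taken, and members at least 1.5-fold higher or lower were counted. The percentile of each median among 10000 random lists, matched in size and mean expression, describes these libraries and is no test. For shares of cells with a UMI, cells were thinned to 2000 UMIs (macrophage comparisons) or 1500 UMIs (T cells), and shallower cells were left out.

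Named genes followed a fixed rule. Among genes with at least 50 UMIs and 20 CPM in 1 library, the 12 highest and 12 lowest by log2 ratio with 5 CPM added to both were taken. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, T-cell receptor, Xist, Y-linked, Gm and Rik genes were left out. Up to 4 members of each list with at least 5 CPM, furthest in the direction of the list's median, were added, and Il34, Csf1r, Csf1, Ptprz1 and Sdc1 were always included. Some genes that this rule takes are not reported here. Genes printed outside this rule are said to be so where they appear.

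The lists, the markers, the named-gene rule, the filters and 17 processing alternatives were fixed before the data were examined. The alternatives covered other scalings (TMM from edgeR and median of ratios from DESeq2, used for size factors only), looser filters (200 genes, 20% mitochondrial) and stricter filters (1000 genes, 5%), doublets kept, resolution 0.5, each library clustered alone, other expression floors (none and 20 CPM), cycling cells left out (at least 2 UMIs of 8 cell-cycle genes), thinning, cells weighted equally, other gates and all filtered cells. After the data were seen 4 were added: BM without the barcodes it shares with GVHD, unnamed myeloid clusters added, macrophages of the T-cell libraries, and T cells of the macrophage libraries.

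On simulated counts drawn from the real library totals and gene means, with 200 genes changed, the interval held the true ratio for 96.6% of genes in each comparison between IL34KO and WT recipients (20620 genes in macrophages, 18953 in T cells). All 24 genes named by the rule had been changed, and 0 unchanged genes passed 1.5-fold. The simulated counts were Poisson draws without variation between cells, libraries or animals, so they show nothing about such variation. For the changed genes alone the interval held the true ratio for 93% in macrophages and 94% in T cells. A list of unchanged genes fell at percentile 95.8 in macrophages and 3.98 in T cells, so percentiles near these also arise without a change. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 (with its Scrublet), igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.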

Results

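Colon cells were studied in mice that had received bone marrow alone (BM) or bone marrow with spleen cells, a transplant that leads to graft-versus-host disease (GVHD), in which donor T cells attack the tissues of the recipient. The series asks whether interleukin 34 (IL-34) made by the epithelium acts on macrophage polarization and on proinflammatory T cells. IL-34 is a ligand of CSF1R, the receptor on which macrophages depend for survival and differentiation. The 6 single-cell RNA libraries held sorted donor CD11b+ CD64+ macrophages of BM mice, of GVHD mice, of wild-type (WT) recipients and of IL-34-deficient (IL34KO) recipients, and sorted donor T cells of WT and IL34KO recipients. In this order they held 5874, 4169, 8084, 8913, 18360 and 15205 barcodes, with 43660889, 60139133, 105927133, 105041239, 114425913 and 84394258 UMIs. The median barcode held 3192, 9302, 8977, 8174, 5301.5 and 3474 UMIs. After the filters and the removal of doublets 4378, 2608, 4906, 6031, 12986 and 7882 cells remained. Each group was 1 library, so there is no replicate error and no test below. Brackets after a value hold its exact 95% interval, which covers counting error only.

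Il34 was looked at first, since it may check the labels. The gene (ENSMUSG00000031750) lies on the minus strand of chromosome 8 at 110741829 to 110805924 of mm10. Over all barcodes it stood at 1.47 CPM (1.13 to 1.87; 64 UMIs) in BM, 0.482 (0.323 to 0.693; 29 UMIs) in GVHD, 1.76 (1.51 to 2.03; 186 UMIs) in the WT macrophage library and 2.30 (2.02 to 2.61; 242 UMIs) in the macrophage library labelled IL34KO. The T-cell libraries had 1.18 CPM (0.989 to 1.40; 135 UMIs) for WT and 1.55 (1.30 to 1.84; 131 UMIs) for the library labelled IL34KO. In epithelial cell-like cells of the macrophage libraries Il34 was at 3.36 CPM (2.45 to 4.49; 362 cells) in WT and 5.42 (4.49 to 6.48; 918 cells) in the library labelled IL34KO, a ratio of 1.61 (1.14 to 2.33). In those of the T-cell libraries it was at 3.21 CPM (2.29 to 4.37; 930 cells) and 4.85 (3.52 to 6.51; 792 cells), a ratio of 1.51 (0.963 to 2.38). Il34 was therefore not lower in either library labelled IL34KO. Which part of the gene was deleted is not given in the sources used here, and a tag outside the deleted part checks nothing. The epithelial values rest on few UMIs, 45 in WT and 120 in the library labelled IL34KO for the macrophage libraries, and 40 and 44 for the T-cell libraries. Both limits hold wherever Il34 is named below.

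Among the receptors, Csf1r (chromosome 18, 61100598 to 61132149) was at 747 CPM (737 to 756) in the monocyte/macrophage-like cells of BM, 513 (506 to 520) in GVHD, 483 (476 to 490) in WT and 504 (497 to 511) in the library labelled IL34KO. T cell-like cells of the T-cell libraries had 30.8 CPM in WT and 34.7 in the library labelled IL34KO. Csf1, the other ligand of this receptor, stood at 16.0, 21.1, 14.5 and 11.7 CPM in the same macrophage classes and at 46.4 and 51.6 CPM in the T cell-like cells. Ptprz1, a second IL-34 receptor, had 4, 2, 1 and 0 UMIs in the macrophage classes and 1 and 0 in the T cell-like cells. Sdc1, a syndecan that also binds IL-34, was at 18.5 CPM in BM, 121 in GVHD, 108 in WT and 114 in the library labelled IL34KO, against 5.87 and 6.03 in the T cell-like cells. Without the barcodes that BM shares with GVHD, described below, Sdc1 was at 5.85 CPM in BM. In the main class of each library Il34 itself was at 0.772, 0.144, 0.419, 0.297, 0.0805 and 0.251 CPM.

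Monocyte/macrophage-like cells made up 83.2% (82.1 to 84.3) of the BM library, 72.6% (70.9 to 74.3) of GVHD, 54.6% (53.2 to 56.0) of WT macrophages and 49.0% (47.7 to 50.2) of the macrophage library labelled IL34KO. These shares can be set by the sort, and unnamed clusters kept out of every class held 7.24%, 8.74%, 21.3% and 15.3% of the cells. They also rest on the clustering: with each library clustered alone they were 45.3%, 61.8%, 66.5% and 56.4%, in another order. Epithelial cell-like cells were 0.754%, 1.88%, 7.38% (6.66 to 8.15) and 15.2% (14.3 to 16.2) of these libraries. With the looser filters they were 1.86%, 4.59%, 11.7% and 19.3%, and with the stricter ones 0.244%, 0.612%, 3.33% and 8.75%. Conventional dendritic cell-like cells were 0.662%, 6.98%, 7.87% and 4.76%, neutrophil-like cells 0%, 0.307%, 5.61% and 9.43%, and T cell-like cells 4.71%, 8.55%, 2.85% and 5.29%. At clustering resolution 0.5 no cluster of these libraries was dendritic cell-like. With the stricter filters neutrophil-like cells were 1.56% (1.20 to 2.00) of WT and 1.78% (1.42 to 2.21) of the library labelled IL34KO, so no order is read from them. Fibroblast-like cells were 2.03% of BM. All BM shares here count 2015 of 4378 cells whose barcodes were also found in GVHD with more UMIs there, a matter taken up below. The libraries of sorted T cells held 26.1% (25.4 to 26.9) T cell-like cells in WT and 24.7% (23.7 to 25.6) in the library labelled IL34KO. Monocyte/macrophage-like cells were 54.4% (53.6 to 55.3) and 53.0% (51.9 to 54.1) there, epithelial cell-like cells 7.16% and 10.0%, and unnamed clusters 7.78% and 8.03%. Neutrophil-like cells were 0.824% and 0.571% there, and 5.50% and 5.82% with the stricter filters.

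**Figure D1:**
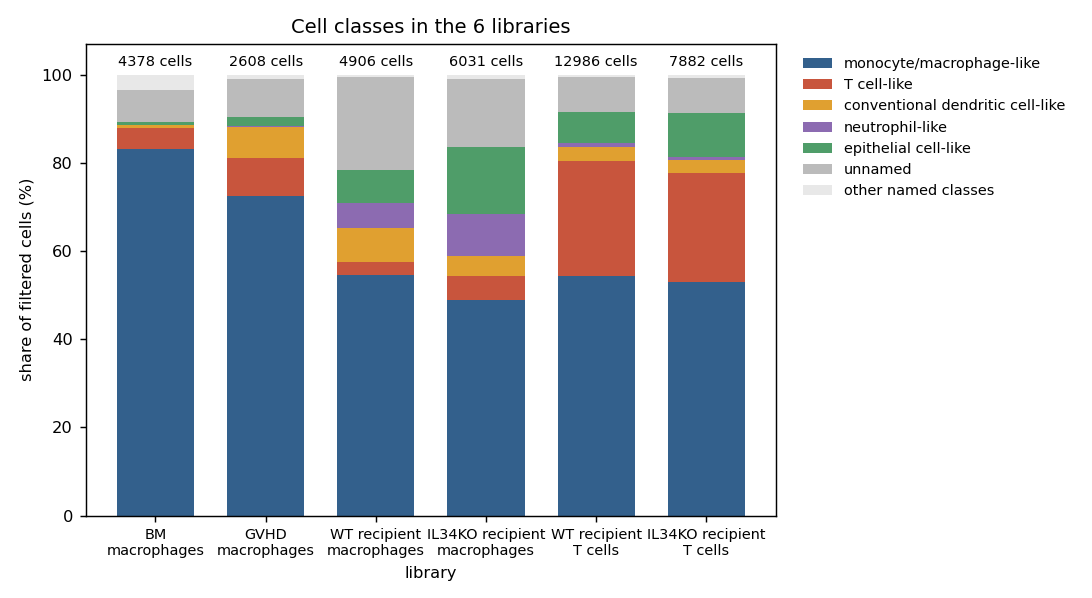
Stacked bars give the share of filtered cells (%) in each cell class for the 6 libraries, with the number of cells above each bar. Monocyte/macrophage-like cells take 83.2% of BM and 54.4% of the WT T-cell library, where T cell-like cells take 26.1%.

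To describe donor macrophages in GVHD, the monocyte/macrophage-like cells of GVHD (1894 cells) were compared with those of BM (3644 cells). Genes of resident tissue macrophages were lower in GVHD, with 16 of 22 measured members at least 1.5-fold lower, 0 higher and a median log2 ratio of −1.67 (−1.69 to −1.65). Genes of glycolysis and hypoxia (21 of 23 higher, 1.13), of the interferon-γ response (20 of 26 higher, 1.03) and of monocytes (14 of 19 higher, 0.84) were higher. Both arginine-using enzymes were higher in GVHD: Nos2, inducible nitric oxide synthase, 9.37-fold (8.30 to 10.6; 82.7 against 8.83 CPM) and Arg1, arginase 1, 7.45-fold (7.0 to 7.94; 253 against 34.0 CPM). Retnla, a product of alternatively activated macrophages, was 51.5-fold lower (44.4 to 60.2; 4.24 against 218 CPM).

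The BM and GVHD libraries shared barcodes. Of the BM barcodes, 2486 were found in GVHD with more UMIs there, and these were 42.3% of BM barcodes and 11.1% of BM UMIs, and 1599 of the 3644 monocyte/macrophage-like BM cells. The comparison was therefore also made without them, an alternative chosen after the data were seen, which left 2045 BM cells of the class. Without them Nos2 was 125-fold higher in GVHD (80.2 to 209), Arg1 25.9-fold (23.1 to 29.3), Chil3 25.7-fold (23.9 to 27.7) and Slc7a2, which imports arginine, 62.4-fold (51.5 to 76.3). List medians moved little, to −1.79 for resident genes (17 of the list lower), 1.37 for glycolysis and hypoxia, 1.24 for interferon-γ and 0.94 for monocyte genes. Folds below use all barcodes, and the value without shared barcodes follows for each named gene that it moved by more than 1.5 times and for other leading genes. Counting intervals over all barcodes do not cover the effect of the shared barcodes, as the 2 values of Nos2 show.

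The proinflammatory macrophage list had 12 members higher and 4 lower in GVHD of 23 measured, with a median of 0.69 (0.63 to 0.76) at percentile 100 of matched random lists. Without shared barcodes its median was 0.79. Besides Nos2, its members Cxcl9, a T-cell-attracting chemokine (920 against 192 CPM, 4.78-fold, 4.66 to 4.92), Fpr2 (4.73-fold) and Acod1, which makes itaconate (3.86-fold), were higher, and 8.68-, 8.46- and 5.73-fold higher without shared barcodes. The alternative activation list had 10 members higher and 6 lower of 22, with a median of 0.47 (0.40 to 0.53) and a mean of −0.07. Within it Chil3 (677 against 93.6 CPM, 7.24-fold, 6.97 to 7.51), Ccl17 (6.46-fold, 60.2-fold without shared barcodes) and Pdcd1lg2, which encodes PD-L2 (4.23-fold, then 7.86-fold), were higher, and Retnla lower. This median was 0.11 with each cell weighted equally, 0.18 with no expression floor, 0.21 after thinning and 0.25 with each library clustered alone. These settings keep the shared barcodes in BM, which were 43.9% of its cells of the class and 10.8% of their UMIs. Equal weights for cells therefore count the shared barcodes more.

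Of the resident genes, Cd163, the haemoglobin scavenger receptor, was 70.4-fold lower (50.7 to 101; 0.862 against 60.7 CPM), Lyve1 305-fold (130 to 942; 0.12 against 36.6 CPM) and Gas6 27.1-fold (4.24 against 115 CPM). Monocyte genes higher in GVHD included Hp, haptoglobin (4.50-fold, 4.07 to 4.98), and Fn1, fibronectin (3.71-fold), which were 7.31- and 5.64-fold higher without shared barcodes. Genes of the Csf1r axis had a median of −0.26 (−0.29 to −0.23; 3 higher and 5 lower of 17), with Maf 2.56-fold, Inpp5d 2.03-fold and Csf3r 1.77-fold lower. The interferon-γ list was led by Gbp2 (593 against 133 CPM, 4.46-fold, 4.32 to 4.61), Serpina3g (4.15-fold) and Iigp1 (3.62-fold), at 7.71-, 6.86- and 5.14-fold without shared barcodes. Type I interferon genes went the other way, with a median of −0.32 (−0.39 to −0.25; 2 higher and 6 lower of 23), and Ifit3 was 4.51-fold, Isg20 2.71-fold, Ifit2 2.24-fold and Ifit1 2.03-fold lower. In monocyte-like clusters alone the log2 ratios of Fn1 (−0.60), Isg20 (0.02) and Ifit1 (1.08) changed direction. This setting, here and below, keeps the BM barcodes shared with GVHD, and 68 of the 86 genes had a value in it.

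Antigen-presentation genes of MHC class II had a median of −0.04 (−0.07 to −0.01; 2 higher and 5 lower of 13), and H2-Eb1 (1.86-fold), H2-Ab1 (1.83-fold), H2-Ob (1.63-fold) and Cd74 (1.61-fold) were lower in GVHD. The MHC class I list had a median of 0.31 (0.27 to 0.34; 5 higher and 2 lower of 16) and a mean of −0.34. Its members Tap1 (2.05-fold, 1.96 to 2.14), Psmb8 (1.96-fold), Psmb9 (1.95-fold) and Tap2 (1.70-fold) were higher, and H2-Q6 was 116-fold lower (80.9 to 172). For H2-Q6 a strain difference between the libraries, taken up under the other observations, cannot be told apart from GVHD. Complement genes (−0.24, −0.26 to −0.21) had 4 members higher and 4 lower of 14, among them C2 (9.82-fold), C5ar1 (3.01-fold) and C3ar1 (2.37-fold), all lower. The chemokine list (−0.50, −0.55 to −0.45) had 7 higher and 9 lower of 20, with the monocyte-attracting Ccl7 20.4-fold (24 against 492 CPM), Cxcl1 18.0-fold, Ccl12 17.4-fold and Ccl8 8.70-fold lower. Repair and growth-factor genes had a median of −0.01 (−0.21 to 0.11; 8 higher and 8 lower of 21), with Bmp2 71.6-fold (42.4 to 132), Igf1 10.2-fold (9.18 to 11.4), Mmp13 7.14-fold and Sparc 5.08-fold lower. In monocyte-like clusters alone Cxcl1 (log2 ratio 3.58), C3ar1 (0.45) and H2-Eb1 (0.15) were not lower.

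The glycolysis and hypoxia list (median 1.13, 1.07 to 1.16, percentile 100) was led by the lactate exporter Slc16a3 (4.02-fold, 3.73 to 4.35, and 6.26-fold without shared barcodes), Hilpda (2.90-fold), Pgam1 (2.76-fold) and Pgk1 (2.63-fold). Genes of oxidative phosphorylation were also higher in GVHD (0.69, 0.68 to 0.72; 25 higher and 1 lower of 33), among them Cox8a (1.88-fold), Atp5l (1.85-fold), Cox5b (1.83-fold) and Cox4i1 (1.79-fold). Lipid-handling genes had a median of 0.13 (0.08 to 0.23) and a mean of −0.01, with 5 higher and 4 lower of 22. Spp1, osteopontin, was 3.08-fold (2.91 to 3.26), Fabp5 2.79-fold, Lpl 1.91-fold and Abcg1 1.61-fold higher. Antimicrobial genes were higher (0.54, 0.52 to 0.57; 8 higher and 0 lower of 18), with Wfdc21 10.6-fold (8.34 to 13.5), Saa3 3.58-fold (5.52-fold without shared barcodes), Clec4e 3.38-fold and Prdx5 2.61-fold. Without shared barcodes BM had 1 UMI of Wfdc21, a ratio of 706 (126 to 27903). Cell-cycle genes had 9 higher and 0 lower of 22 (0.49, 0.40 to 0.56), among them Ccnb2 and Nusap1 (1.93-fold each), Ccnb1 (1.91-fold) and Pclaf (1.73-fold). Stress and dissociation genes, a sign of handling and RNA quality, were lower in GVHD (−0.66, −0.69 to −0.65; 0 higher and 11 lower of 21), with Hspb1 15-fold, Hspa1a 3.55-fold, Hspa1b 3.21-fold and Atf3 2.91-fold lower. In monocyte-like clusters alone the log2 ratios of Saa3 (−1.97), Fabp5 (−0.43), Clec4e (−0.47), Nusap1 (−1.51), Hspa1a (1.51) and Hspa1b (0.83) changed direction.

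Among the other genes furthest apart, Ksr2 (8.51-fold), Mmp8 (7.77-fold), the coagulation factor F7 (7.67-fold), Inhba, a subunit of activin (149 against 19.6 CPM, 7.59-fold, 7.0 to 8.25), Flt1 (7.15-fold), Cd24a (6.66-fold), Sdc1 (6.54-fold, 6.01 to 7.13) and F10 (401 against 72.5 CPM, 5.52-fold) were higher in GVHD. Without shared barcodes Ksr2 was 58.9-fold (39.8 to 91.3), Mmp8 37.6-fold, F7 32.7-fold, Inhba 33.8-fold, Flt1 24.9-fold, Cd24a 19.1-fold, Sdc1 20.6-fold and F10 12.5-fold higher. In monocyte-like clusters alone Mmp8 was lower (log2 ratio −0.41). At the other end, the non-coding gene Mir99ahg (0.311 against 142 CPM) was 456-fold lower (266 to 857). Cd4 (0.623 against 120 CPM) was 193-fold (132 to 296), Plxna4 168-fold (113 to 262), Hpgd, which degrades prostaglandins, 129-fold (89.2 to 195), Ptprm 58.0-fold, Fcrls 57.5-fold, Adgrl3 50.8-fold and Tanc2 (25.3 against 463 CPM) 18.3-fold (17.2 to 19.5) lower. P3h2 had 0 UMIs in GVHD and 2457 in BM (75.9 CPM), 1056-fold lower against a floor of 3 counts over the class. The lower end of its counting interval was 858-fold.

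To compare shares of cells, each cell was thinned to 2000 UMIs, which left out 1124 of the 3644 BM cells and 70 of the 1894 GVHD cells (median depths 4967 and 17191.5 UMIs). With the shared barcodes out of BM the numbers were 109 of 2045 cells and 12231 UMIs. T cell-like cells, which should lack these genes, served as background, with median depths of 3457 UMIs in BM and 3465 in GVHD. Nos2 had a UMI in 8.94% (7.67 to 10.3) of thinned GVHD cells against 2.46% (1.89 to 3.14) of BM cells and 0.207% (0.0563 to 0.528) without shared barcodes, with backgrounds of 1.29%, 0.68% and 0.82%, so the last share lay below its background. Unthinned, the shares were 24.2%, 4.58% and 0.489%. Arg1 was found in 23.1% (21.2 to 25.1) of GVHD cells, 6.11% of BM cells and 0.517% without shared barcodes, with backgrounds of 1.94%, 4.08% and 0% and unthinned shares of 45.6%, 9.91% and 1.22%. Cxcl9 was found in 51.9% (49.5 to 54.2), 18.8% and 6.61%, with backgrounds of 10.3%, 6.12% and 0.82% and unthinned shares of 78.5%, 32.5% and 16.7%. Ccl7 went the other way, with 2.58% (1.90 to 3.41) in GVHD and 23% (21.4 to 24.7) in BM, backgrounds of 0% and 1.36% and unthinned shares of 11.5% and 28.8%. Cd163 was in 0.110% (0.0133 to 0.396) and 5.71% (4.84 to 6.69), with backgrounds of 0% and 0% and unthinned shares of 1.58% and 10.5%.

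The class was held by different clusters in the 2 libraries. A mature macrophage-like cluster, led by Tanc2, Mir99ahg and Ccl7, held 1794 BM cells and 12 GVHD cells. A cluster led by Tnfsf9, Lyz1, Fap and Fn1 held 322 and 692 cells, a cluster led by Cc2d2b, Ksr2 and Gpnmb 91 and 541, and a shallow cluster led by Ccdc162 and Thbs1 1182 and 406. The BM counts of clusters include the shared barcodes, 1599 of its 3644 cells of the class, and are not given without them. Markers of other cells measured within the class also differed. Some of these sets, here and below, share genes with the macrophage lists. Cd4 is a T-cell marker and a resident gene, and Ccl17 a dendritic cell marker and an alternative activation gene. Acod1 is a neutrophil marker and a proinflammatory gene, and Sdc1 a plasma cell marker and a gene of the Csf1r axis. Their medians therefore also hold differences of macrophage genes and do not measure other cells in the class. Dendritic cell markers had a median of 1.06 (6 higher and 1 lower of 10), neutrophil markers 1.71 (5 and 2 of 9), epithelial markers 0.82 (3 and 0 of 6), endothelial markers 0.75 (1 and 1 of 2) and natural killer or innate lymphoid markers 0.05 (2 and 1 of 5). Markers lower in GVHD were those of T cells (−3.34; 0 and 2 of 3), B cells (−2.05; 0 and 3 of 3), plasmacytoid dendritic cells (−2.05; 0 and 3 of 3), fibroblasts (−1.92; 0 and 4 of 4), platelets (−2.31; 0 and 2 of 2) and plasma cells (−0.28; 1 and 2 of 5). The monocyte/macrophage markers themselves had a median of −0.49 (7 and 8 of 26), and no eosinophil, mast cell, γδ T-cell or erythroid marker was measured. TMM scaling raised all log2 ratios by 0.10 and median-of-ratios scaling by 0.13. In monocyte-like clusters alone the monocyte list was lower in GVHD (−0.30) and the stress list at 0.01, the complement list was at 0.48 and the antimicrobial list at −0.06. Without cycling cells the cell-cycle list was at −0.22, and with no expression floor the proinflammatory median was 0.27.

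**Figure D2:**
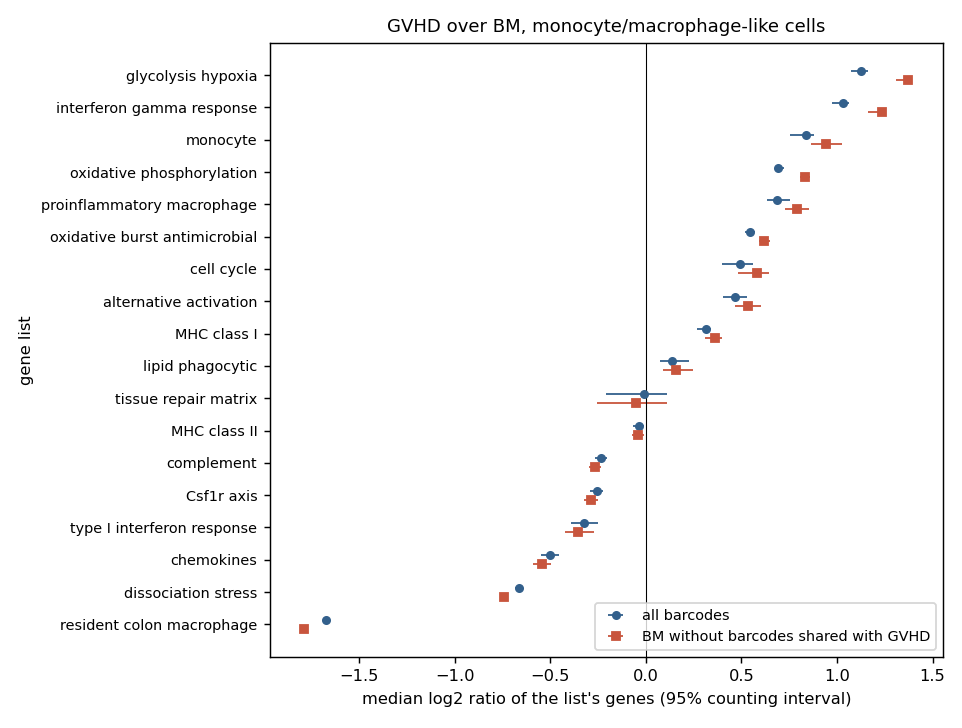
Points give the median log2 ratio, GVHD over BM, of each gene list in monocyte/macrophage-like cells, and bars its 95% counting interval. Circles use all barcodes and squares leave out the BM barcodes shared with GVHD; the resident list lies lowest at −1.67 and −1.79.

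To see how recipient IL-34 bears on macrophages, the monocyte/macrophage-like cells of the library labelled IL34KO (2953 cells) were compared with those of the WT library (2680 cells). Resident macrophage genes were lower in the library labelled IL34KO (0 higher and 5 lower of 17, median −0.36, −0.41 to −0.26), as were chemokines (1 higher and 5 lower of 19, −0.28, −0.32 to −0.24). Mrc1, the mannose receptor, was 2.32-fold lower (2.24 to 2.40; 121 against 281 CPM), Apoe, apolipoprotein E, 2.19-fold (2.17 to 2.21; 1847 against 4038 CPM) and Timd4, a receptor for apoptotic cells, 3.36-fold (2.92 to 3.87; 6.86 against 23 CPM). Nos2 was 1.52-fold higher (1.49 to 1.56; 620 against 406 CPM) and Ccl5 1.59-fold higher (1.57 to 1.61; 1618 against 1016 CPM). These directions rest on the label, since Il34, which was not lower in the library that bears it, may not check it.

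The same comparison in monocyte/macrophage-like cells of the T-cell libraries, chosen after the data were seen, repeated only some of these directions. Nos2 was at 1.07-fold there (1.04 to 1.10), less than in the macrophage libraries, and the proinflammatory list at 0.06 (0.01 to 0.08; 3 higher and 0 lower of 23). The resident list had a median of 0.01 (0.01 to 0.06; 0 higher and 0 lower of 21), and chemokines turned to 0.04 (0.01 to 0.08; 2 and 0 of 19). Whether the macrophage and T-cell libraries come from the same mice is not given in the sources used here, so the 2 pairs were not taken as independent replicates. Mrc1 stood at 378 CPM in WT and 392 in the library labelled IL34KO, Apoe at 7541 and 7597, Timd4 at 31.5 and 33.1, Nos2 at 272 and 292, and Ccl5, now lower, at 954 and 776. Across 1835 genes with at least 50 CPM, log2 ratios of monocyte/macrophage-like cells in the 2 pairs of libraries had a Pearson r of −0.29. Within the macrophage libraries, ratios of these cells and of T cell-like cells had an r of 0.60, although the classes differ. The resident list was lower there in T cell-like (−0.39; 1 higher and 8 lower of 18) and epithelial cell-like cells (−0.36; 0 and 4 of 12) too. These are macrophage genes, for which other classes show a background level. That background would follow a difference in macrophages, so the lower lists there decide nothing, and it may also enter the r of 0.60. These correlations are across genes, which are not independent replicates. No gene of 5398 was at least 1.5-fold higher in both pairs or lower in both, and 3 were opposite.

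The proinflammatory list had 3 members higher and 0 lower of 24 in the library labelled IL34KO, with a median of 0.09 (0.02 to 0.14) at percentile 99.0. With cells thinned to equal UMIs this median was −0.03, so its direction is not settled. Besides Nos2, these included Il12a (17.6 against 10.2 CPM, 1.72-fold, 1.52 to 1.96), and Fpr2 was at 1.33-fold. The alternative activation list had 1 higher and 5 lower of 21 (−0.08, −0.21 to −0.05, percentile 3.81). Of its members Mrc1, Clec10a (1.71-fold), Fn1 (1.69-fold) and Irf4 (1.62-fold) were lower, and Retnla (74.5 against 43.9 CPM) was 1.70-fold higher. Cells with a Retnla UMI were 1.24% (0.849 to 1.75) in WT and 1.49% (1.08 to 2.01) in the library labelled IL34KO after thinning, and 1 WT cell held 44.2% of the WT UMIs. Also lower among resident genes was the fractalkine receptor Cx3cr1 (28.5 against 58.1 CPM, 2.04-fold, 1.90 to 2.20). Chemokines lower there were Ccl12 (2.39-fold, 1.97 to 2.90), Ccl2 (26.4 against 53.2 CPM, 2.02-fold), Ccl7 (1.88-fold) and Ccl8 (1.79-fold). In macrophages of the T-cell libraries their log2 ratios were 0.46, 1.0, 0.35 and 0.04, so all 4 turned. Monocyte genes had a median of −0.13 (−0.19 to −0.12; 0 higher and 1 lower of 19), with Thbs1 at 1.49-fold lower, and genes of the Csf1r axis one of −0.13 (−0.15 to −0.09; 0 and 0 of 17), with Runx1 1.32-fold and Maf 1.31-fold lower.

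The interferon-γ list stood at 0.03 (0.01 to 0.06; 0 and 0 of 26), with Irgm1 at 1.29-fold higher, and type I interferon genes at −0.02 (−0.08 to 0.01; 0 and 2 of 22), with Oasl1 1.77-fold and the RNA sensor Ifih1 2.02-fold lower (97.8 against 197 CPM). MHC class II genes stood at −0.08 (−0.14 to −0.04; 0 and 1 of 13), with H2-Eb2 2.51-fold (2.04 to 3.11) and Cd74 1.20-fold lower, and MHC class I genes at 0.06 (0.04 to 0.09; 0 and 0 of 15), with H2-Q4 1.26-fold and Tapbp 1.11-fold higher. Complement genes were at −0.21 (−0.22 to −0.13; 0 and 1 of 13), with C3ar1 1.34-fold and C1qa 1.21-fold lower. Repair genes were at −0.20 (−0.27 to −0.15; 0 and 3 of 18), with Igf1 1.61-fold and Timp1 1.59-fold lower, and lipid genes at −0.07 (−0.10 to −0.06; 0 and 1 of 22), with Cd36 1.47-fold and Gpnmb 1.34-fold lower. Higher medians were found for oxidative phosphorylation (0.27, 0.24 to 0.29; 0 and 0 of 33), with Uqcr10 1.41-fold and Atp5k 1.39-fold, and for glycolysis and hypoxia (0.14, 0.12 to 0.16; 1 and 0 of 24), with Egln3 1.53-fold and Bnip3 1.31-fold. The cell cycle was at 0.22 (0.15 to 0.27; 1 and 0 of 22), with Mcm6 1.59-fold, Mcm5 1.40-fold and Top2a 1.38-fold (a cell cycle median of 1.27 with each library clustered alone), and antimicrobial genes at 0.10 (0.08 to 0.12; 0 and 1 of 19), with Saa3 1.45-fold and Wfdc21 1.41-fold. Stress genes were lower (−0.22, −0.24 to −0.19; 0 and 1 of 20), with Jund 1.57-fold and Fosb 1.39-fold. In the T-cell libraries, the macrophage medians for oxidative phosphorylation, cell cycle and stress were −0.17, −0.02 and 0.10.

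Among the other genes furthest apart, Reg3b, an antibacterial lectin of the gut epithelium, was 5.25-fold higher in the library labelled IL34KO (4.61 to 6.0; 37.6 against 7.15 CPM). In epithelial cell-like cells of the same libraries it stood at 2864 and 647 CPM, and the thinned share of macrophages with a UMI (8.09%) lay below that of T cell-like cells (11.4%), a background level. Gpx2 (2.05-fold) and Spink4 (1.67-fold) were also far higher in epithelial cell-like cells (1255 and 2245 CPM). Rps27rt (1.91-fold), Hist1h2ap (1.90-fold), Serf1 (1.68-fold), Slc1a2 (1.63-fold), Ly6i (1.59-fold) and Grina (1.56-fold) were higher as well, though Slc1a2 had a log2 ratio of −0.04 at clustering resolution 0.5. Lower genes were the fibroblast activation protein Fap (5.05 against 34.1 CPM, 6.75-fold, 5.79 to 7.91), Cc2d2b (3.63-fold), the lysozyme Lyz1 (87.1 against 237 CPM, 2.73-fold), the stem cell factor Kitl (2.65-fold), Eldr (2.41-fold), Plxdc2 (2.34-fold), Tmem176a (2.27-fold) and Tmem176b (2.08-fold).

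Thinning to 2000 UMIs left out 98 WT cells and 136 cells of the library labelled IL34KO (median depths 12411.5 and 10681 UMIs), with T cell-like cells (5477.5 and 4311 UMIs) as background. Nos2 had a UMI in 28% (26.2 to 29.7) of WT cells and 39.5% (37.7 to 41.4) of cells in the library labelled IL34KO, with backgrounds of 0.826% and 2.93% and unthinned shares of 45.3% and 57.6%. Mrc1 was in 25.3% (23.6 to 27.0) and 13.9% (12.7 to 15.2), with backgrounds of 3.31% and 1.10% and unthinned shares of 50.5% and 32.4%. Apoe was in 62.2% (60.3 to 64.1) and 48.8% (46.9 to 50.7), with backgrounds of 22.3% and 11.4% and unthinned shares of 87.3% and 72.6%. Timd4 was in 3.10% (2.46 to 3.84) and 0.994% (0.661 to 1.43), with backgrounds of 0.826% and 0% and unthinned shares of 9.10% and 3.56%.

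Clusters of the class differed here too. A cluster led by Inhba, Nos2, Clmp and Slc7a2 held 766 WT cells and 1068 cells of the library labelled IL34KO, the monocyte-like clusters led by Plcb1 and Vcan and by Ly6c2, Plac8 and Ly6i held 561 and 671 and 421 and 650, and the clusters led by Tnfsf9, Lyz1 and Fap and by Cc2d2b and Gpnmb held 335 and 144 and 278 and 99. Markers of epithelium (0.45, 0.40 to 0.55; 3 higher and 0 lower of 12) and of neutrophils (0.29, 0.22 to 0.32; 0 and 0 of 10) within the class were higher in the library labelled IL34KO. The share of epithelial cell-like cells was higher there too, while no order is read from the shares of neutrophil-like cells. Other marker medians were −0.17 for monocytes and macrophages (0 and 4 of 26), −0.67 for B cells (0 and 2 of 2), 0.24 for plasma cells (2 and 0 of 5), −0.02 for dendritic cells (0 and 0 of 8), −0.07 for natural killer or innate lymphoid cells (0 and 0 of 5), 0.04 for endothelium (2 members), 0.29 for T cells (1 member), 0.00 for plasmacytoid dendritic cells (2 members) and −0.39 for platelets (1 member). As a scale for the whole comparison, the SD of log2 ratios over genes was 0.20 here (5648 genes). It was 0.87 between GVHD and BM (5986 genes), 0.99 without shared barcodes, and 0.41 between the WT and GVHD macrophage libraries (5773 genes). The labels do not say that the WT and GVHD libraries are the same condition, so they are not a replicate pair. In the last pair Nos2 was 4.91-fold (4.73 to 5.10) and Retnla 10.4-fold (8.86 to 12.2) higher in the WT library. In monocyte-like clusters alone the resident median was −0.01, and Retnla was lower in the library labelled IL34KO (−1.14).

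**Figure D3:**
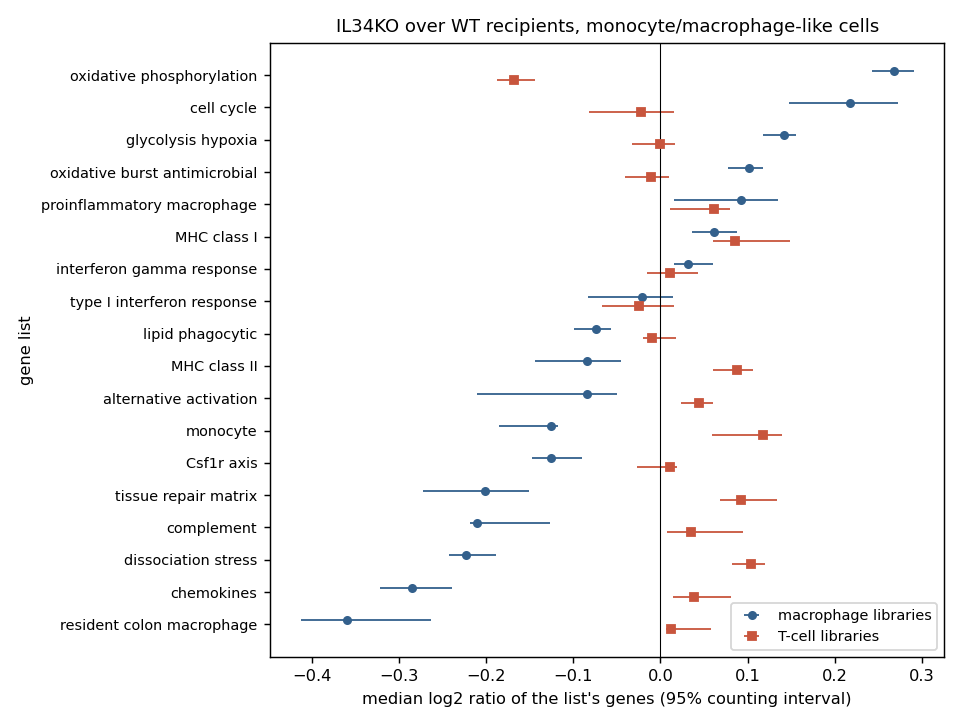
Points give the median log2 ratio, IL34KO-labelled over WT library, of each gene list in monocyte/macrophage-like cells, and bars its 95% counting interval. Circles are the macrophage libraries and squares the T-cell libraries; the resident list lies at −0.36 in the first and 0.01 in the second.

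To see how recipient IL-34 bears on T cells, the T cell-like cells of the T-cell library labelled IL34KO (1943 cells) were compared with those of the WT library (3392 cells). Csf2, which encodes the cytokine GM-CSF, was 5.33-fold higher in the library labelled IL34KO (4.24 to 6.75; 41.6 against 7.81 CPM, 331 and 97 UMIs). Genes of Th17 cells had 3 members higher and 0 lower of 12, Il23r (3.44-fold, 2.27 to 5.33), Il17a (3.29-fold, 2.37 to 4.62) and Il22 (3.67-fold, 2.04 to 6.91), though 1 cell held 42.5% of the Il22 UMIs in that library and the thinned share of cells with Il22 was not higher there. Genes of Th1 and inflammatory T cells (2 higher and 0 lower of 23, median 0.16, 0.08 to 0.18) and of gut homing (0 and 0 of 18, 0.22, 0.13 to 0.28) had medians above those of most matched random lists. Il34 was not lower in this library either, so the directions rest on its label.

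T cell-like cells of the macrophage libraries, an alternative chosen after the data were seen, repeated the Csf2 direction (26 UMIs or 13 CPM in the library labelled IL34KO against 5 UMIs or 4.71 CPM in WT, 2.75-fold, 1.04 to 9.17) and not most lists, of which 16 of 18 changed sign. There the medians were −0.11 for Th1, −0.24 for Th17 and −0.18 for regulatory T cells, and Il17a was lower in the library labelled IL34KO (−1.61), as in cells with a Cd8 UMI and no Cd4 UMI of the T-cell libraries (−0.47). Across 1835 genes with at least 50 CPM, the log2 ratios of T cell-like cells in the 2 pairs of libraries had an r of −0.35. Those of T cell-like and monocyte/macrophage-like cells within the T-cell libraries had an r of 0.78. Of 5438 genes 2 were at least 1.5-fold higher in both pairs, Saa3 among them, 0 lower in both and 14 opposite.

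The Th1 median of 0.16 lay at percentile 99.96, and Hopx (171 against 105 CPM, 1.62-fold, 1.5 to 1.75), Xcl1 (1.41-fold) and Bhlhe40 (1.35-fold), a regulator of Csf2, were higher. Matched random lists themselves had a median above 0, since the median of all genes was 0.07. The Th17 median was 0.22 (0.15 to 0.32), with Ahr at 1.27-fold. Regulatory T-cell genes stood at 0.09 (0.04 to 0.13; 0 and 0 of 19, percentile 70.0), with Itgae 1.45-fold, Klrg1 1.41-fold, Il10 1.40-fold and Ctla4 1.25-fold (601 against 482 CPM). Th2 genes stood at 0.05 (−0.09 to 0.14; 0 and 1 of 7) with a mean of −0.02, among them Il1rl1 at 1.12-fold and Gata3 at 1.05-fold. Cytotoxic genes stood at 0.05 (0.01 to 0.11; 0 and 0 of 21), with granzymes Gzmb at 1.45-fold (727 against 499 CPM, 1.40 to 1.51) and Gzma at 1.30-fold and the receptor Klrc1 at 1.20-fold. Exhaustion genes had a median of 0.09 (0.05 to 0.15; 0 and 0 of 17; Nr4a1 1.40-fold, Lag3 1.29-fold, Rgs16 1.28-fold) and naive or memory genes one of 0.11 (0.02 to 0.17; 0 and 0 of 12; Klf2 1.35-fold, Lef1 1.22-fold). Gut homing genes included P2rx7 (1.34-fold) and the integrin Itga1 (1.31-fold). Activation genes had a median of 0.07 (0.02 to 0.10; 0 and 0 of 21; Myc 1.47-fold, Cd226 1.19-fold) and T-cell receptor signalling genes one of 0.07 (0.06 to 0.12; 0 and 0 of 21; Cd3g 1.19-fold, Skap1 1.15-fold).

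Of the lists shared with macrophages, stress genes were higher in the library labelled IL34KO (0.29, 0.23 to 0.32; 3 and 0 of 20), with Egr3 1.75-fold (a log2 ratio of −0.07 over all filtered cells), Hspa1a 1.74-fold and Junb 1.46-fold. Oxidative phosphorylation was lower (−0.19, −0.23 to −0.17; 1 higher and 2 lower of 33), with Uqcr11 1.54-fold and Atp5k 1.53-fold. MHC class I genes were at 0.16 (0.07 to 0.29; 2 and 0 of 15), with Tap2 1.80-fold (1.63 to 2.00), H2-T22 1.56-fold and Psmb9 1.37-fold, and interferon-γ genes at 0.10 (0.05 to 0.15; 1 and 0 of 25), with Irgm1 1.87-fold (1.43 to 2.44) and Cxcl10 1.37-fold. Type I interferon genes were at −0.06 (−0.13 to 0.08; 0 and 1 of 20), with Oas1a 1.54-fold and Rsad2 1.42-fold lower, and MHC class II genes at 0.00 (−0.07 to 0.05; 0 and 1 of 11), with H2-DMb2 2.50-fold lower (1.55 to 4.20). Glycolysis and hypoxia stood at 0.00 (−0.05 to 0.05; 0 and 0 of 23), with Eno1 at 1.46-fold lower, and the cell cycle at −0.03 (−0.07 to 0.03; 0 and 0 of 22), with Stmn1 at 1.11-fold lower. Among cells with a Cd4 UMI and no Cd8 UMI, the medians were 0.09 for Th1, 0.29 for Th17 and −0.24 for type I interferon (0 higher and 7 lower of 20), and among cells with a Cd8 UMI and no Cd4 UMI 0.24 for Th1.

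Other genes furthest apart were often those of other cells or of the whole library. Il1rapl1 (43.7 against 10.3 CPM, 4.24-fold) was also at 39.8 against 8.23 CPM in the monocyte/macrophage-like cells. Lyz1 (36.3 against 9.58 CPM, 3.79-fold), Saa3 (3.33-fold) and Gdf15 (3.10-fold) were higher in the library labelled IL34KO, and they stood at 250, 136 and 243 CPM in its monocyte/macrophage-like cells. In 1 cell lay 62.7% of its Saa3 UMIs, 26.6% of those of Lyz1 and 18.5% of those of Gdf15. Rnaset2b (2.83-fold), Rpa3 (2.57-fold), Rnaset2a (2.54-fold), Zfp36, which destabilises cytokine mRNA (96.5 against 44.8 CPM, 2.15-fold), Sdhd (2.15-fold) and Cmss1 (1.90-fold) were higher too. Lower genes included the histones Hist1h2ap (37.8 against 267 CPM, 7.07-fold, 6.28 to 7.98), Hist1h2ae (3.07-fold) and Hist1h2ab (2.38-fold), and the seminal vesicle genes Svs4 (7.44-fold) and Svs5 (6.33-fold), of whose WT UMIs 1 cell held 44.2% for Svs5. Gstp1 (2.44-fold), Galnt18 (2.33-fold), F10 (1.71-fold), Romo1 (1.66-fold) and the epithelial genes Agr2 (2.47-fold) and Zg16 (1.81-fold) were lower as well. Over all filtered cells the log2 ratios of Saa3 (−0.15), Agr2 (0.25) and Zg16 (0.87) changed direction. Hist1h2ap had log2 ratios of −3.05, −2.82 and −2.64 in monocyte/macrophage-like, T cell-like and epithelial cell-like cells of the T-cell libraries and of 0.93, 1.20 and 1.01 in those of the macrophage libraries.

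After thinning to 1500 UMIs, which left out 568 WT cells and 281 cells of the library labelled IL34KO (median depths 2811 and 3013 UMIs), Csf2 had a UMI in 1.31% (0.924 to 1.80) of WT cells and 3.85% (2.98 to 4.89) of cells in the library labelled IL34KO. The monocyte/macrophage-like cells used as background (6761 and 7265 UMIs) had 0% and 0.0794%, and the unthinned shares were 2.18% and 6.64%. Il17a was in 0.283% (0.122 to 0.557) and 0.782% (0.417 to 1.33), with backgrounds of 0% and 0.0265% and unthinned shares of 0.649% and 0.978%. Gzmb was in 32.3% (30.5 to 34.0) and 36.2% (33.8 to 38.5), with backgrounds of 0.333% and 0.556% and unthinned shares of 41.6% and 47.2%. Il22 was in 0.106% and 0.0602%, against the direction of its CPM, so no order is read from it.

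T cell-like clusters held 1120 WT cells and 692 cells of the library labelled IL34KO (led by Gzma, Gzmb and Cd8a), 682 and 418 (Lef1), 586 and 333 (Ccl1 and Xcl1), 609 and 302 (Nkg7) and 395 and 198 (cycling). Marker medians within the class were 0.09 for T cells (0 and 0 of 19), 0.18 for monocytes and macrophages (2 higher and 0 lower of 25), −0.29 for epithelium (1 and 3 of 13), −0.01 for dendritic cells (0 and 3 of 10), −0.15 for neutrophils (1 and 2 of 6), 0.10 for natural killer or innate lymphoid cells (1 and 0 of 10), −0.06 for γδ T cells (2 and 1 of 5) and −0.06 for plasma cells (0 and 1 of 4). Those of plasmacytoid dendritic cells (3 members) stood at 0.30, of endothelium (2 members) at 0.36, and of B cells, mast cells and platelets (1 member each) at −0.08, 0.38 and 0.88. Over all barcodes and not within the class, the share of mitochondrial UMIs was 5.51% in the WT T-cell library and 9.46% in the one labelled IL34KO, and 7.13% and 5.42%, the other way, in the macrophage libraries. The SD of log2 ratios over 6203 genes was 0.19. With TMM scaling the regulatory T-cell median was 0.01, and over all filtered cells the Th1 median was 0.04.

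**Figure D4:**
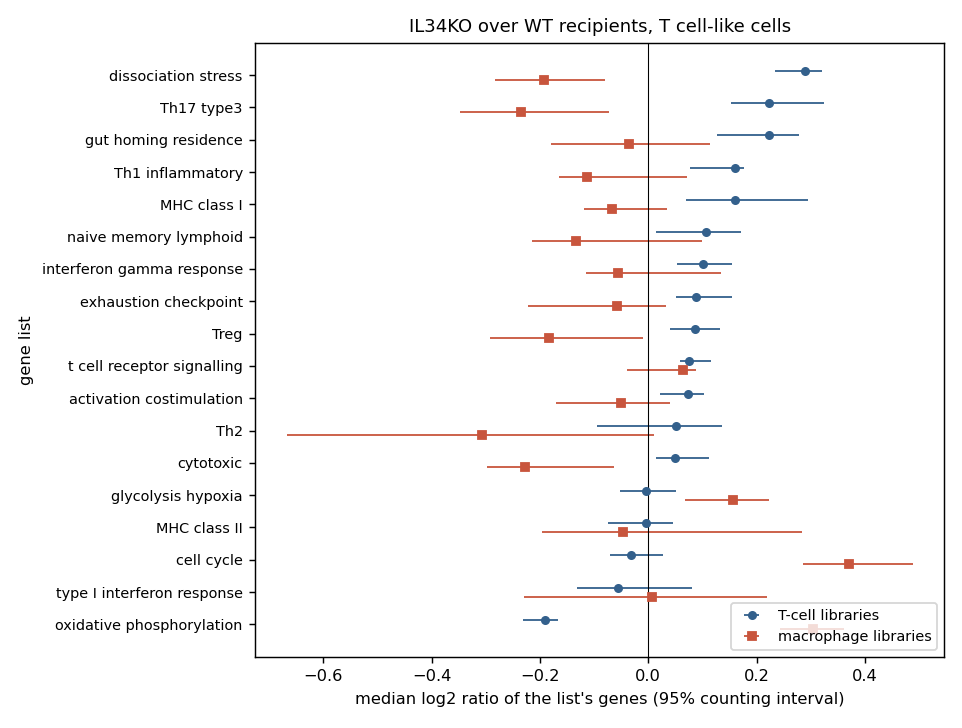
Points give the median log2 ratio, IL34KO-labelled over WT library, of each gene list in T cell-like cells, and bars its 95% counting interval. Circles are the T-cell libraries and squares the macrophage libraries; the Th1 list lies at 0.16 in the first and −0.11 in the second.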

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

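The test of shared barcodes against chance was chosen after their number had been seen, as were the comparisons without them and across the other pair of libraries.

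Cells outside the sorted population were counted because the comparisons do not use them. In the libraries of sorted donor T cells, monocyte/macrophage-like cells were 54.4% of the WT library and 53.0% of the library labelled IL34KO, and epithelial cell-like cells 7.16% and 10.0%. In the libraries of sorted macrophages, T cell-like cells were 4.71% of BM, 8.55% of GVHD, 2.85% of WT and 5.29% of the library labelled IL34KO. Innate lymphoid-like cells, with Gata3, Il5 and Il1rl1, were 0.914% of BM. Both BM shares are of all filtered BM cells, 46.0% of which had barcodes shared with GVHD. A cluster with the seminal vesicle genes Svs5 and Svs4 held 22 cells of the WT and 11 of the IL34KO-labelled T-cell library.

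The comparison of IL34KO-labelled with WT libraries gave list medians of opposite sign in macrophages of the macrophage libraries and T cells of the T-cell libraries. Oxidative phosphorylation stood at 0.27 and −0.19, and stress genes at −0.22 and 0.29. The difference was not tested. The signs went with the pair of libraries and not with the cell type: T cells of the macrophage libraries had 0.30 and −0.19 for the 2 lists, and macrophages of the T-cell libraries −0.17 and 0.10.

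BM and GVHD shared 2502 barcodes, where the other 14 pairs of libraries shared 5 to 75, which argues against chance. In GVHD 2486 of them held more UMIs, a median of 17432 against 1506.5, with a ratio of 11.6 that varied little (11 to 12.3 from the 5th to the 95th percentile). Their log10 UMIs in the 2 libraries had a Pearson r of 0.995. For 500 of them drawn at random, a median of 93.4% of the genes of the BM barcode were detected in the same GVHD barcode, against 71.4% in another. Of the 1244 GVHD barcodes with at least the median of 17432 UMIs, 99.9% were shared. The 12 named genes lower in GVHD had, in the shared BM barcodes, 3.42% (3.04 to 3.83) of their level in the other BM barcodes, 84.7 against 2475 CPM, where GVHD itself had 64.5 CPM. The 12 named genes higher in GVHD without shared barcodes stood at 2364 CPM in the shared BM barcodes. They stood at 101 CPM in the other BM cells and 2410 in GVHD. Molecules of the GVHD library counted again in the BM library are therefore a candidate explanation, and the test could have come out the other way. No biological explanation was tested, since the design names none.

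Resident macrophage genes were lower in the macrophage library labelled IL34KO, where Il34 was not lower, which may check nothing. RNA from epithelial cells is argued against as the cause: its estimated share in macrophages was 0.817% in WT and 1.19% in the library labelled IL34KO, a difference of 0.370 percentage points, which is too small for a median of −0.36. A different mix of clusters cannot be told apart, since the median was −0.0129 (−0.08 to 0.06) in monocyte-like clusters and −0.163 (−0.22 to −0.14) in the cluster led by Inhba and Nos2, an interval that holds the bound of −0.18. A difference between these 2 macrophage libraries alone may account for the pattern, since macrophages of the T-cell libraries had a median of 0.0125 (0.01 to 0.06). The list was also lower in T cell-like (−0.39) and epithelial cell-like cells (−0.36) of these 2 macrophage libraries. This does not decide, since macrophage genes are at a background level in those cells, which would follow a difference in macrophages. An effect of the recipient's IL-34 stays open, as untested.

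Csf2 was higher in T cells of the library labelled IL34KO, where Il34 was not lower. A few cells with many UMIs are argued against by the thinned shares, which count each cell once and had a ratio of 2.94 (1.93 to 4.53). The most loaded cell held 10.57% of the UMIs, just over a bound of 10% written before the value was seen, and the weight was put on the shares only afterwards. Handling of the whole library cannot be told apart, since the stress medians of its macrophages, 0.103 (0.08 to 0.12), and epithelial cells, 0.0357 (0.01 to 0.07), lay under the 0.15 set for it and above the 0 set against it. In the T cells themselves the stress median was 0.29 (0.23 to 0.32). Of the barcodes of this library 56.4% passed the filters, against 76.6% in the WT T-cell library. A difference between the T-cell libraries alone cannot be told apart: T cells of the macrophage libraries had a ratio of 2.75 (1.04 to 9.17), past the bound of 2 set against it, but that bound took no account of a WT count as near the floor as 5 UMIs (26 in the other library), and an effect of the recipient's IL-34 stays open.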

How the results depend on the processing

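The settings without shared barcodes, with unnamed clusters added, in macrophages of the T-cell libraries and in T cells of the macrophage libraries were chosen after the data were seen. No paired analysis was possible because each group was 1 library and the labels name no replicate or animal. The mature macrophage-like cluster alone was not run, as it held 12, 20 and 14 cells in GVHD, WT and the library labelled IL34KO against 1794 in BM. Counting intervals do not hold differences between preparations, which limit every value here. A change of direction was counted in these numbers only for results at least 1.5-fold from 1 at first. Of 1358 single-gene values for GVHD over BM, 641 moved less than their interval, 704 moved further and 13 changed direction, with 668 higher and 637 lower than the first value. The numbers were 844, 439 and 29 of 1312 for macrophages of recipients (663 higher, 456 lower) and 1122, 227 and 24 of 1373 for T cells (462 higher, 815 lower). Of 306 list values each, 129, 194 and 228 stayed within their interval, 175, 112 and 78 moved further, and 2, 0 and 0 changed direction, but no list of the recipient comparisons had been 1.5-fold from 1. Of the values of results under 1.5-fold, 23 of 187, 27 of 306 and 42 of 306 list medians changed sign before rounding, and 38 of 672 and 49 of 816 single-gene values in macrophages and T cells of recipients. Where a value changed, the cause was not tested.

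For GVHD over BM, the proinflammatory median of 0.69 was 0.79 with TMM, 0.82 with median of ratios, 0.77 without mitochondrial and ribosomal genes, 0.27 with no expression floor, 0.76 with a floor of 20 CPM, 0.76 with strict filters, 0.34 over all filtered cells, 0.48 without cycling cells, 0.45 with cells weighted equally, 0.63 after thinning, 0.44 in monocyte-like clusters and 0.79 without shared barcodes. The alternative activation median of 0.47 was 0.57, 0.60 and 0.54 with the first 3 of these settings, 0.18 with no floor, 0.53 with strict filters, 0.25 with each library clustered alone, 0.11 with cells weighted equally, 0.21 after thinning and 0.54 without shared barcodes. Except for the last of each list, these settings keep the shared barcodes in BM.

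For IL34KO-labelled over WT macrophages, the proinflammatory median of 0.09 was 0.15 with each library clustered alone, −0.03 after thinning and 0.15 with unnamed clusters added. The alternative activation median of −0.08 was −0.27 over all filtered cells, −0.02 in monocyte-like clusters and 0.04 in macrophages of the T-cell libraries. For T cells, the Th1 median of 0.16 was 0.04 over all filtered cells, 0.24 in the Cd8 gate and −0.11 in T cells of the macrophage libraries. The regulatory T-cell median of 0.09 was 0.01 with TMM, 0.02 with median of ratios, 0.00 over all filtered cells, 0.04 with cells weighted equally and −0.18 in T cells of the macrophage libraries. Il34 was not lower in the libraries labelled IL34KO.

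The share of monocyte/macrophage-like cells in BM (83.2%) was 87.9% with strict filters, 87.9% with doublets kept, 45.3% with the library clustered alone, 90.4% at resolution 0.5, 86.5% without shared barcodes and 90.5% with unnamed clusters added. In GVHD (72.6%) it was 83.2% with strict filters, 78.8% with doublets kept, 61.8% clustered alone, 84.6% at resolution 0.5 and 81.4% with unnamed clusters added. In WT (54.6%) it was 51.3% with loose filters, 58.8% with strict filters, 57.7% with doublets kept, 66.5% clustered alone, 49.2% at resolution 0.5 and 75.9% with unnamed clusters added. In the library labelled IL34KO (49.0%) it was 46.0% with loose filters, 56.4% clustered alone, 34.5% at resolution 0.5 and 64.3% with unnamed clusters added. T cell-like cells in the WT T-cell library (26.1%) were 24.9% with loose filters, 23.2% with strict filters and 24% with doublets kept, and in the library labelled IL34KO (24.7%) 20.1%, 26.1% and 22.4%. Of the 36 values 27 lay outside the first interval, and 19 were higher and 17 lower.

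Directions of results at least 1.5-fold from 1 changed, as log2 ratios, in monocyte-like clusters alone, where shared barcodes were kept in BM. For GVHD over BM these were the monocyte list (−0.30), the stress list (0.01), Mmp8 (−0.41), Fn1 (−0.60), Isg20 (0.02), Ifit1 (1.08), H2-Eb1 (0.15), C3ar1 (0.45), Cxcl1 (3.58), Fabp5 (−0.43), Saa3 (−1.97), Clec4e (−0.47), Nusap1 (−1.51), Hspa1a (1.51) and Hspa1b (0.83). For IL34KO-labelled over WT it was Retnla (−1.14), which stood at 0.00 with each library clustered alone, while Slc1a2 was at −0.04 at resolution 0.5.

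In macrophages of the T-cell libraries the reversed genes among those first at least 1.5-fold apart were Hist1h2ap (−3.05), Gpx2 (−0.42), Ccl5 (−0.30), Ly6i (−0.14), Grina (−0.25), Serf1 (−0.07), Spink4 (−0.32), Egln3 (−0.03), Fap (0.10), Lyz1 (0.50), Cc2d2b (0.16), Timd4 (0.07), Plxdc2 (0.13), Mrc1 (0.05), Apoe (0.01), Tmem176a (0.21), Tmem176b (0.12), Clec10a (0.33), Fn1 (0.11), H2-Eb2 (0.12), Ccl12 (0.46), Ccl2 (1.0), Ccl7 (0.35), Ccl8 (0.04), Igf1 (0.18) and Jund (0.22). Of the 42 genes under 1.5-fold 29 changed sign there, among them Uqcr10 (−0.31) and Atp5k (−0.69), as did 13 of the 18 lists.

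In T cells of the macrophage libraries those first at least 1.5-fold apart that reversed were Lyz1 (−0.02), Gdf15 (−1.92), Zfp36 (−0.67), Irgm1 (−0.18), Tap2 (−0.20), H2-T22 (−0.24), Hspa1a (−0.37), Hopx (−0.13), Il17a (−1.61), Hist1h2ap (1.20), Hist1h2ae (1.0), Agr2 (0.87), Hist1h2ab (0.72), Romo1 (0.65), F10 (0.80), Oas1a (0.71), H2-DMb2 (0.16), Uqcr11 (0.58) and Atp5k (0.72). Of the 51 genes under 1.5-fold 30 changed sign there, as did 16 of the 18 lists. Over all filtered cells of the T-cell libraries they were Saa3 (−0.15), Egr3 (−0.07), Agr2 (0.25) and Zg16 (0.87), and in the Cd8 gate Il17a (−0.47).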

Other observations

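The comparisons of epithelial cells, of T cells in BM and GVHD and of genes shared by both pairs of libraries, and the choice of the genes named here, were made after the data were seen; the test of the strain hypothesis was set before its 2 genes had been looked at in epithelial cells.

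In epithelial cell-like cells, which no sort aimed at, some genes differed the same way in both pairs of libraries, which may come from the same mice, although the log2 ratios of the pairs had an r of 0.05 across 1835 genes with at least 50 CPM, and of 0.0982 across 6389 genes, which are not independent replicates. The antibacterial lectin Reg3b was at 2864 CPM in the macrophage library labelled IL34KO and 647 in WT (4.43-fold, 4.33 to 4.53), and at 944 and 534 CPM in the T-cell libraries (1.77-fold, 1.71 to 1.83). Its relative Reg3g was 2.66-fold (432 against 162 CPM) and 1.59-fold higher (223 against 140 CPM). Ido1, which degrades tryptophan and is induced by interferon-γ, was 1.74-fold and 2.25-fold higher, Ddx60 1.73-fold and 1.65-fold, Slfn4 1.58-fold and 2.11-fold, and Fut9 1.73-fold and 2.14-fold. Reg4, a marker of secretory cells, was lower in both (118 against 210 CPM, and 88.4 against 166). In all, 8 genes of 6389 were at least 1.5-fold higher in both pairs, 3 lower in both and 12 opposite. Il34 was not lower in the epithelial cells of either library labelled IL34KO.

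In T cell-like cells, GVHD (223 cells) was set against BM without shared barcodes (143 cells). Gzma was 2.94-fold (2.68 to 3.24), Csf2 2.58-fold (1.67 to 4.11; 82.9 against 32.2 CPM), Ifng 1.59-fold (1.39 to 1.82), Lef1 3.11-fold (2.31 to 4.27) and Il10 3.97-fold (2.03 to 8.66) higher in GVHD. Il23r was 16.3-fold (8.20 to 36.8), Cxcr3 5.06-fold (2.31 to 12.2) and the memory factor Tcf7 4.72-fold (2.95 to 7.78) lower, and Gzmb was at 0.965-fold (0.877 to 1.06). Against a floor of 3 counts over the class, Gzmf, with 55 UMIs in GVHD and 0 in BM, was 10.9-fold higher, and Il17a, with 20 and 0, 3.95-fold. The lower ends of their counting intervals were 8.55-fold and 2.93-fold. List medians were −0.54 for cytotoxic genes (5 higher and 9 lower of 21), −0.54 for Th17 (4 and 8 of 16), −0.10 for Th1, 0.11 for regulatory T cells and 0.45 for glycolysis and hypoxia (10 and 0 of 24). MHC class II genes stood at 2.52 (11 and 0 of 11), beside macrophage transcripts such as Il1b (20.2-fold, 13.3 to 32.5).

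In both pairs of libraries Xcl1 was higher in T cell-like cells of the libraries labelled IL34KO, 3.63-fold (3.07 to 4.33) in the macrophage libraries and 1.41-fold in the T-cell libraries. Lrrk2 was 2.59-fold and 1.34-fold lower. In monocyte/macrophage-like cells Cxcl3 was 1.38-fold and 2.00-fold higher.

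The MHC class I genes H2-Q6 and H2-Q7 stood at 93.1 and 184 CPM in BM monocyte/macrophage-like cells without shared barcodes and at 428 and 1152 in BM T cell-like cells. They stood at 0.719 and 13.1 in GVHD macrophages, 2.23 and 17.4 in WT and 2.38 and 18.1 in the library labelled IL34KO. In epithelial cell-like cells of GVHD, WT and the library labelled IL34KO, H2-Q6 stood at 48.6, 59.9 and 57.5 CPM and H2-Q7 at 161, 190 and 204. Shared barcodes were not taken out of the few epithelial cell-like cells of BM. These cells went the other way, with 3.99 CPM (0.101 to 22.2; 1 UMI) of H2-Q6 and 24 (8.79 to 52.1; 6 UMIs) of H2-Q7, and a hypothesis about donor cells alone does not cover this. Donor cells of another mouse strain in the BM library are a hypothesis for the levels in BM macrophages and T cells, tested with 2 other genes of the same pattern. Over the 4 libraries labelled as WT and IL34KO recipients Zbtb10 was 22.48-fold higher in epithelial than in monocyte/macrophage-like cells (20.1 to 25.3), past the 3-fold asked of each gene. But its level in epithelial cell-like cells was 59.9 CPM in BM (15 UMIs), 54.5 in GVHD and 47.3 in those 4 libraries, so unlike H2-Q6 it was no lower in BM. Pxdc1 was at 0.195-fold (0.157 to 0.239), short of that bound. It was hardly detected in epithelial cell-like cells, at 1.70 CPM over those 4 libraries and with 1 UMI each in BM and GVHD. Its low ratio therefore does not speak against a strain difference. Of the 2 genes 1 passed the bound and 1 did not, and the ratio also depends on which cells express a gene. The test therefore does not decide, and a strain difference cannot be told apart from others. The strains of the donors are not given in the sources used here, so a strain difference may also bear on other folds of GVHD over BM.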
